A study of Mus musculus with 20 samples.

How the data were processed

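RNA from the left lung lobe of C57Bl6 mouse embryos was hybridized to Affymetrix Mouse430A_2 arrays, one animal per array. The 20 arrays fall into 4 groups of 5: controls with a floxed GR gene and mutants lacking GR in mesenchymal cells, each at E16.5 and at E18.5. The deposited table holds log2 values that the authors made with GCRMA (background correction, scaling between arrays and one summary value per probe set), per the submitters' processing notes; the GCRMA version is not given in the sources used here. The values were not transformed again. Per array, the median over all probe sets was between 5.70 and 5.87, and between 13088 and 13319 probe sets lay above a log2 value of 4. Precision is limited by the number of arrays, 5 per group.

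The table has 22690 probe sets, of which 20380 name 1 gene, 691 name several, 1555 name none and 64 are array controls. For each of the 12393 genes with a single-gene probe set, the probe set with the highest mean over the 20 arrays was used. Genes were tested when their log2 value was above 4 in at least 5 of the 20 arrays, which left 8068. A log2 value below 4 is called dim. Probe sets naming several genes or none were left out of the gene tests and counted separately.

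Group means were fitted to all 20 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that the 4 groups share one estimate of the spread. The contrasts were mutant against control at each stage, E18.5 against E16.5 in each genotype, and the difference between the mutant effects at the 2 stages (interaction). Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Errors of log2 differences are limma standard errors (SE). Errors of group means are standard deviations (SD) over 5 animals.

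Before the data were examined, 43 gene lists with 818 entries were fixed (cell types, pathways and tissues that a dissection could carry over), together with the design, the alternatives and the rule for naming genes. Of the entries, 741 matched a gene on the array. Lists with 5 or more tested members, 36 in all, were tested with limma's camera, two-sided, at a preset correlation between genes of 0.01, adjusted with Benjamini-Hochberg over the lists of one comparison. Camera was repeated with the correlation estimated for each list. Because that ended every camera call in each comparison, a further test was added after the values were seen: an exact two-sided permutation test of each list's mean per animal, adjusted over the 36 lists.

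The rule for named genes took, for each mutant comparison, Nr3c1, the 12 called genes with the largest rise and the 12 with the largest fall, and for each list with a camera call or with 2 or more called members up to 4 called members with the largest change (2 members as values where none was called). For development in controls it took the 10 largest rises, the 10 largest falls and list members in the same way, and for the interaction the 10 called genes with the smallest p. Genes without a proper symbol were passed over. The report gives all genes that the rule names, except for development in controls, where it gives the 20 largest changes and, of the list members, a few examples chosen after their values were seen. Genes named outside this rule are marked as chosen after their values were seen.

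Overlap between the stages was tested with a one-sided Fisher exact test. The slope of the E18.5 mutant effect on the developmental change of the controls was computed with the 5 E18.5 controls divided 3 and 2, so that no array entered both axes, as the mean over the 10 divisions, with a jackknife SE and a two-sided permutation of the genotype labels in 100 regroupings. The stage position of an array is its place on the line from the E16.5 to the E18.5 control mean (0 and 1), with each control left out of the means it was placed against. This measure was added after the values were seen. Xist was compared with the Y-linked genes Eif2s3y, Kdm5d and Uty to tell female from male embryos.

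The alternatives covered the arrays in the fit, the filter on dim genes, quantile normalization, median centring, the choice of probe set, the variance model, array weights, the replicate number, sex, blood, the thresholds, and leaving out each array in turn. Covariates for stage position and for the poly-A spike-in controls were added after the values were seen. The code was tested on simulated data with the same groups. At E16.5 and E18.5 it recovered 95.0% and 97.5% of the genes given a log2 change of 1, with 4.05% and 6.11% false calls, and it called 1 unshifted list at E18.5. Of the genes given a log2 change of 0.5 it recovered 62.5% and 65.0%. The simulated noise was independent between genes, so the list test was not checked under correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3. No genome assembly was used, and chromosomes are those of RefSeq gene records matched by gene symbol.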

Results

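The arrays measured messenger RNA in the left lung lobe of mouse embryos at E16.5, before the peak of fetal glucocorticoids, and at E18.5, shortly before birth. Each stage had 5 control and 5 mutant animals. The mutants carried a Cre transgene driven by the Col1a2 locus that removes the glucocorticoid receptor gene (GR, Nr3c1) in mesenchymal cells. Correlations between arrays of one group were 0.979 to 0.995 in E16.5 controls, 0.969 to 0.996 in E18.5 controls, 0.985 to 0.995 in E16.5 mutants and 0.978 to 0.995 in E18.5 mutants. By Xist and the Y-linked genes, 1 of 5 embryos was female among the E16.5 controls, 5 of 5 among the E16.5 mutants, 3 of 5 among the E18.5 controls and 2 of 5 among the E18.5 mutants. At E16.5, sex and genotype therefore largely coincide.

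Nr3c1 on chromosome 18 was lower in all mutants than in all controls of the same stage. Its brightest probe set read 8.78 ± 0.22 (SD, n = 5) in E16.5 controls and 7.07 ± 0.45 in E16.5 mutants, a log2 difference of -1.72 (SE 0.17, limma adjusted p = 1.66e-05) that left 30.4% of the control level. At E18.5 it read 9.42 ± 0.22 in controls and 7.79 ± 0.19 in mutants, a difference of -1.62 (SE 0.17, adjusted p = 1.62e-06) that left 32.5%. The second probe set was lower by similar amounts, with 31.6% left at E16.5 and 35.0% at E18.5. The third, dim probe set had 46.1% left at E16.5, where it did not pass the test over all probe sets (adjusted p = 0.0699), and 34.0% at E18.5 (adjusted p = 0.000140). Where these probe sets lie relative to the deleted part of the gene is not known from the files, and the whole lobe also holds epithelial and endothelial cells, which keep the receptor by design.

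**Figure D1:**
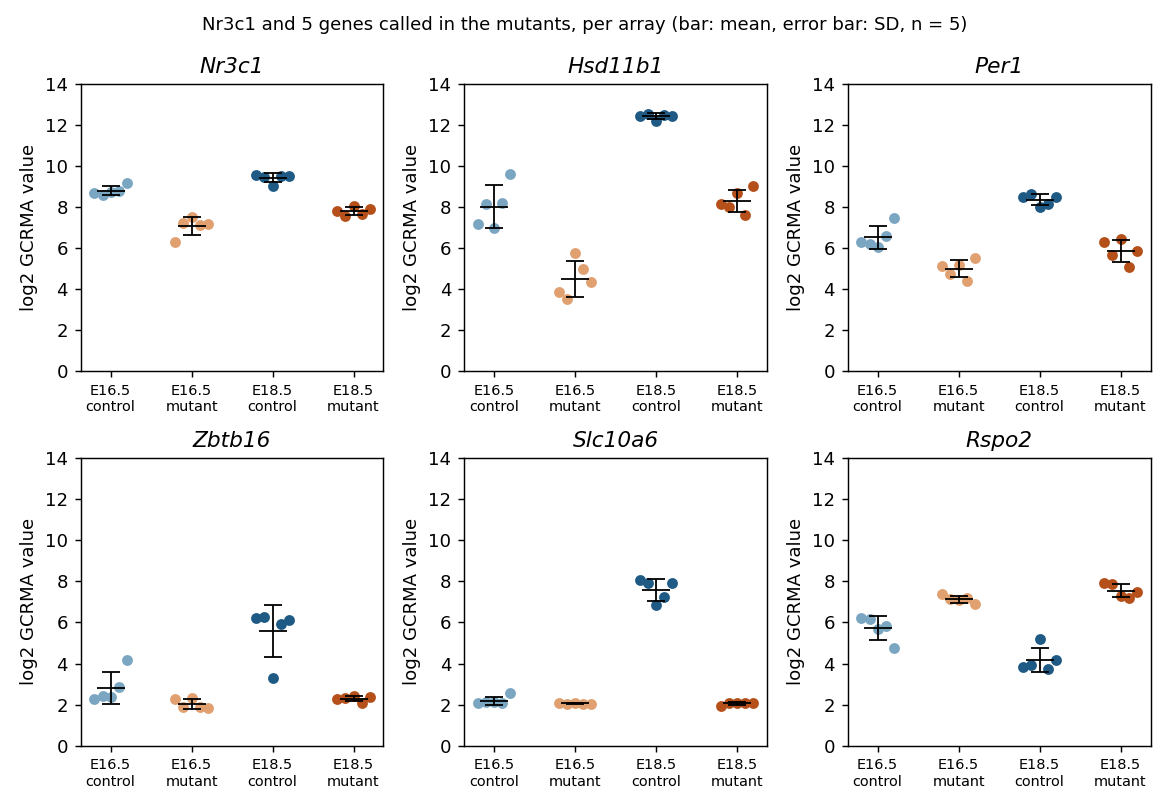
Log2 GCRMA value (y axis) of Nr3c1 and 5 genes called in the mutants, for each array of the 4 groups; bars are means and error bars are SD over 5 animals. Nr3c1, Hsd11b1, Per1 and Rspo2 separated mutants from controls at both stages, while Slc10a6 and Zbtb16 had dim means in all groups but the E18.5 controls.

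At E16.5 the comparison asks what loss of mesenchymal GR does before the late rise of fetal glucocorticoids. The largest difference was in Hsd11b1, which regenerates active glucocorticoid from its inactive form. It fell by 3.52 on the log2 scale (SE 0.43, adjusted p = 0.000224), from 8.02 ± 1.03 to 4.50 ± 0.89 (SD, n = 5). Cldn1, a tight junction protein, fell by 2.05 (SE 0.20), and G0s2, an inhibitor of triglyceride lipase, fell by 2.00 (SE 0.15). The circadian repressor Per1 fell by 1.53 (SE 0.27), Hif3a, a hypoxia-inducible factor subunit, fell by 1.35 (SE 0.23) and Dgat2, which makes triglyceride, fell by 1.34 (SE 0.21). Smaller falls passed in the lysophosphatidic acid receptor Lpar1 (-0.71, SE 0.11), the smooth muscle phosphatase inhibitor Ppp1r14a (-0.60, SE 0.07), the glycogen regulator Ppp1r3c (-0.60, SE 0.08). They also passed in Igsf5 (-0.59, SE 0.11), the collagen and elastin crosslinking enzyme Lox (-0.58, SE 0.11) and the matrix proteoglycan Ogn (-0.46, SE 0.09). The Wnt agonist Rspo2 rose by 1.39 (SE 0.27), the mesenchymal homeobox gene Prrx1 by 0.73 (SE 0.13), the circadian receptor Nr1d2 by 0.63 (SE 0.10) and the orphan receptor Nr2f1 by 0.47 (SE 0.10). In each of the 16 genes with the largest changes, all 5 mutant arrays lay beyond all 5 controls. For an unselected gene chance gives this in a share of 0.00794, which is no test here, since these genes were selected for large changes.

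In all, 20 of 8068 genes passed at E16.5 (4 higher and 16 lower in mutants, limma with Benjamini-Hochberg), and 356 had an unadjusted p under 0.05. With sex as a covariate 8 of the 20 still passed (Nr3c1, Rspo2, Hsd11b1, Cldn1, G0s2, Lpar1, Ppp1r14a and Ppp1r3c), and all 20 kept their direction. With the replicate number as a block in the fit 12 genes passed, all lower, so Rspo2, Prrx1, Nr1d2 and Nr2f1 lost their calls. Leaving out mutant replicate 4 or mutant replicate 5 left 13 calls each. Per1 lost its call without mutant replicate 4 (log2 change -1.38), Igsf5 without control replicate 5 or mutant replicates 4 or 5 (-0.54, -0.55 and -0.54), and Lox without control replicates 1, 4 or 5 or mutant replicates 2, 4 or 5 (-0.60 to -0.52). Rspo2 kept its call only without control replicates 1 or 2, and was at 1.14 to 1.45 without any other E16.5 array. Nr2f1 (0.43 to 0.49) and Ogn (-0.48 to -0.39) lost theirs without any of 9 of the 10 E16.5 arrays. The exceptions were mutant replicate 1 for Nr2f1 and control replicate 1 for Ogn. With the E18.5 arrays, which share the estimate of the spread, counted too, Nr2f1 lost its call without any of 15 arrays and Ogn without any of 17.

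Among the gene lists at E16.5, the glucocorticoid-induced genes were lowest, with a median of -0.28 over 29 members (camera adjusted p = 1.20e-15, adjusted p = 0.110 with an estimated correlation). Of these, 2 members were called lower, Per1 and Hif3a, and 2 were lower adjusted over the list alone. The list of steroid receptors and glucocorticoid metabolism had 2 of 7 members called lower (Nr3c1 and Hsd11b1), and 1 higher and 3 lower adjusted over the list alone. Its median was -0.01 and its mean -0.74 (adjusted p = 9.32e-05, adjusted p = 0.0616 with an estimated correlation). Fibrillar collagen and interstitial matrix genes had 1 of 29 lower, Ogn, and 4 adjusted over the list alone (adjusted p = 9.32e-05, adjusted p = 0.253 with an estimated correlation). FGF signalling had 0 of 15 called and 2 lower adjusted over the list alone (adjusted p = 0.000155, adjusted p = 0.152 with an estimated correlation), with values of -0.65 for the receptor Fgfr4 and -0.33 for Fgf18. Elastic fibre genes had 1 of 17 lower, Lox, and 3 adjusted over the list alone (adjusted p = 0.00405, adjusted p = 0.253 with an estimated correlation), and lipofibroblast genes had 1 of 15 lower, Dgat2, and 1 adjusted over the list alone (adjusted p = 0.00792, adjusted p = 0.219 with an estimated correlation). Wnt signalling was the list called higher, with 1 of 18 members called, Rspo2, and 1 adjusted over the list alone (median 0.15, adjusted p = 0.0379, adjusted p = 0.152 with an estimated correlation).

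A further 6 lists were called lower at E16.5 with 0 members called over all genes. Alveolar type I genes had a median of -0.15 (adjusted p = 0.00139, adjusted p = 0.532 with an estimated correlation), with Hopx at -0.58 and the sodium channel subunit Scnn1g at -0.43. Basement membrane genes had a median of -0.12 (adjusted p = 7.55e-05, adjusted p = 0.419 with an estimated correlation), with Col4a4 at -0.49 and Col15a1 at -0.43. Endothelial genes had a median of -0.05 (adjusted p = 0.00193, adjusted p = 0.429 with an estimated correlation), with Ednrb at -0.57 and Robo4 at -0.38. Genes of growth arrest and cyclin-dependent kinase inhibition had a median of -0.07 (adjusted p = 0.0285, adjusted p = 0.253 with an estimated correlation), with Gadd45b at -0.53 and Gadd45g at -0.50, and 1 member lower adjusted over the list alone. Ion and water transport had a median of -0.12 (adjusted p = 0.0288, adjusted p = 0.672 with an estimated correlation), with Nedd4l at -0.55. Immediate-early genes had a median of -0.16 (adjusted p = 0.0288, adjusted p = 0.601 with an estimated correlation), with Egr1 at 0.51 and Zfp36 at -0.44. The other 5 of these lists had 0 members called adjusted over the list alone.

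By the exact permutation test of list means per animal, 0 of 36 lists passed at E16.5 (smallest adjusted p = 0.0952). The glucocorticoid-induced, steroid and Wnt lists had an exact p of 0.00794, the smallest that 5 against 5 animals allow, with 5 of 5 mutants beyond the controls. After adjustment over 36 lists, even that smallest p can pass only if more lists than these have a small p. The lack of calls by this test therefore says little about these lists. Camera with an estimated correlation also called 0 lists, and 6 had an unadjusted p under 0.05. With sex as a covariate camera called 10 lists, all lower: Wnt signalling (adjusted p = 0.0543), ion transport (0.0845) and immediate-early genes (0.0799) lost their calls. E16.5 control replicate 5 was the only female control and also had the highest stage position of the E16.5 controls (0.21, the others -0.09 to 0.043). A loss of calls without this array can therefore not be assigned to its sex or to its stage position. Leaving it out left 4 camera calls: glucocorticoid-induced genes (1.79e-10), steroid receptors and metabolism (0.00168), fibrillar collagen (0.00991) and FGF signalling (0.0169). The adjusted p of the 9 other lists was then 0.0886 to 0.383. The growth arrest list also lost its call without control replicates 2 or 4 or mutant replicates 1 or 2 (0.0576 to 0.157), ion transport without the same arrays (0.0542 to 0.288), immediate-early genes without mutant replicates 1 or 2 (0.238 and 0.0974), and Wnt signalling without control replicates 1, 2 or 3 or mutant replicates 2, 3, 4 or 5 (0.0539 to 0.110). Markers of cardiac muscle passed only without control replicate 4 (0.00322), ciliated cells and mitosis without mutant replicate 2 (0.0126 each), epithelial lineage without mutant replicates 3 or 5 (0.0318 and 0.0360), and type II and club cells without mutant replicate 5 (0.0133 and 0.0360).

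At E18.5 the same loss was compared when fetal glucocorticoids are high. The 2 deepest falls were in genes with dim mutant means. The transporter Slc10a6 fell by 5.53 (SE 0.17, adjusted p = 5.00e-14), from 7.60 ± 0.53 to 2.07 ± 0.06 (SD, n = 5), and the methyltransferase Inmt fell by 5.46 (SE 0.64). The dipeptidase Dpep1 fell by 4.95 (SE 0.44), xanthine dehydrogenase Xdh fell by 4.67 (SE 0.47), Hsd11b1 fell by 4.12 (SE 0.43) and carbonic anhydrase Car4 fell by 3.85 (SE 0.72). The adhesion adaptor Lims2 (-3.74, SE 0.20), the amino acid transporter Slc7a10 (-3.73, SE 0.27), the monooxygenases Fmo2 (-3.69, SE 0.39) and Fmo1 (-3.66, SE 0.44), the matrix protein Spon1 (-3.53, SE 0.34) and the iron-binding lipocalin Lcn2 (-3.52, SE 0.73) followed. The mutant means of Slc10a6, Inmt, Lims2 and Slc7a10 were dim, as were those of Zbtb16, Pdk4, Adm and Saa3, so the sizes of their falls are limited by the floor of the values.

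The strongest rise at E18.5 was again in Rspo2 (3.37, SE 0.27, adjusted p = 6.28e-08). Next came the cartilage collagen gene Col9a1 (3.26, SE 0.50), the embryonic claudin Cldn6 (3.18, SE 0.50), the polysialyltransferase St8sia2 (2.46, SE 0.20), Col9a3 (2.34, SE 0.49) and the cell adhesion gene Cntn1 (2.32, SE 0.19). The eosinophil chemokine Ccl11 (2.15, SE 0.31), the spindle protein Psrc1 (2.14, SE 0.41), the class II histocompatibility gene H2-Eb1 (2.14, SE 0.28), the proteoglycan Vcan (2.10, SE 0.27), Igdcc4 (2.09, SE 0.20) and Scara3 (2.07, SE 0.58) were the other large rises. In 18 of these 24 genes, all 5 mutants lay beyond all 5 controls (0.00794 by chance for an unselected gene, which these are not). The exceptions were Col9a1, Cldn6, Col9a3, Psrc1 and Car4 with 3 of 5 mutants and Scara3 with 0. The control means of Col9a3 and Cntn1 were dim, as were those of Prrx2, Myl2, Cenpe, Cdc45 and Ccl2, so the sizes of their rises, and their order, are limited by the floor of the values.

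Of 8068 genes, 2784 passed at E18.5 (1502 higher and 1282 lower in mutants), 1060 of them with a change of at least 1.5-fold. One control animal, replicate 3, lay between the stages in overall expression (0.704 on an axis from 0 to 1), and without it 3355 genes passed. With stage position as a covariate 584 genes passed, of which 407 were among the 2784. This covariate is computed from the same expression values and nearly coincides with genotype at E18.5. It lay at 0.452 to 0.769 in mutants and at 1.02 to 1.09 in all controls but replicate 3. That fit therefore cannot separate the mutant effect from stage position. In it, 15 of the 139 genes named for E18.5 had the opposite sign. These were Scara3 (-0.25), Akr1c14 (0.21), Hc (0.83), Scd1 (0.53), Lyz2 (0.17), Chad (0.38), Cyp2f2 (0.08), Pdlim3 (-0.01), Msln (0.58), Hmmr (-0.11), Kif20a (-0.04), Dhrs3 (0.21), Bmp2 (0.41), Gpam (0.23) and Icam1 (0.16).

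Glucocorticoid-induced genes fell as a group at E18.5. Of 29 members, 22 were lower and 1 was higher, both over all genes and adjusted over the list alone (median -1.34, camera adjusted p = 2.50e-13, adjusted p = 0.193 with an estimated correlation). Examples are Lcn2, the transcription factor Zbtb16 (-3.27, SE 0.44), the metabolic kinase Pdk4 (-3.17, SE 0.20) and the sulfotransferase Sult1a1 (-2.52, SE 0.39). In the list of steroid receptors and metabolism, 4 of 7 were lower and 1 was higher, also adjusted over the list alone (adjusted p = 0.0180, adjusted p = 0.239 with an estimated correlation), among them the ketosteroid reductase Akr1c14 (-1.92, SE 0.52) and H6pd (-0.61, SE 0.12), which supplies cofactor to the Hsd11b1 enzyme. Of 15 immediate-early genes 11 were lower and 1 higher, also adjusted over the list alone (median -0.82, adjusted p = 6.18e-06, adjusted p = 0.239 with an estimated correlation), with Fos at -1.86 (SE 0.36), Klf2 at -1.12 (SE 0.22), Klf4 at -1.06 (SE 0.25) and Dusp1 at -1.02 (SE 0.12).

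Genes of cell division were higher in the mutants. All 29 mitosis genes were higher, also adjusted over the list alone (median 1.01, adjusted p = 9.50e-10, adjusted p = 0.397 with an estimated correlation), such as Hmmr (1.40, SE 0.37), the motors Cenpe (1.33, SE 0.27), Kif23 (1.29, SE 0.33) and Kif20a (1.28, SE 0.31). Of 27 DNA replication genes 26 were higher, also adjusted over the list alone (median 0.88, adjusted p = 1.11e-12, adjusted p = 0.239 with an estimated correlation), including Chaf1b (1.66, SE 0.24), Mcm10 (1.62, SE 0.31), Pola1 (1.58, SE 0.28) and Cdc45 (1.57, SE 0.35). E18.5 control replicate 3 had a mean of 9.19 over the mitosis list, against 7.89 to 7.98 in the other controls and 8.51 to 9.73 in the mutants. The list means of only 3 of 5 mutants for mitosis (exact permutation adjusted p = 0.0429) and 4 of 5 for DNA replication (0.0357) therefore lay beyond all controls. The inhibitors of cyclin-dependent kinases Cdkn2b (-1.90, SE 0.41) and Cdkn1a (-1.39, SE 0.12) fell, as did Gadd45g (-0.93, SE 0.24), while Gas2 rose (0.91, SE 0.18). Their list, with 3 higher and 7 lower of 16 and the same counts adjusted over the list alone, was not called by camera (adjusted p = 0.0834) but passed the exact permutation test of list means (-0.27, 5 of 5 mutants beyond the controls, adjusted p = 0.0318).

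Several lists of epithelial genes were lower at E18.5. Of 17 alveolar type I genes, 15 were lower and 1 was higher, also adjusted over the list alone (median -0.75, adjusted p = 1.40e-06, adjusted p = 0.239 with an estimated correlation). The water channel Aqp5 (-1.89, SE 0.33), Rtkn2 (-1.89, SE 0.45) and Scnn1g (-1.58, SE 0.28) fell, and Igfbp2 rose (1.69, SE 0.32). Of 11 club cell genes 7 were lower, also adjusted over the list alone (median -0.61, adjusted p = 0.000875, adjusted p = 0.341 with an estimated correlation), with Scgb3a1 at -2.66 (SE 0.71), Chad at -1.07 (SE 0.38) and Cyp2f2 at -0.69 (SE 0.26). Alveolar type II and surfactant genes had 6 of 21 lower and 1 higher, and 7 lower and 1 higher adjusted over the list alone (median -0.45, adjusted p = 0.0296, adjusted p = 0.615 with an estimated correlation), with Mlc1 at -1.88 (SE 0.40), complement Hc at -1.42 (SE 0.50), the desaturase Scd1 at -1.30 (SE 0.42) and the lysozyme Lyz2 at -1.24 (SE 0.32). The type II call was lost without E18.5 mutant replicate 4 (adjusted p = 0.0840). Ion and water transport had 8 of 13 lower, also adjusted over the list alone (median -0.91, adjusted p = 0.000233, adjusted p = 0.341 with an estimated correlation), led by the epithelial sodium channel subunits Scnn1a (-2.85, SE 0.41), Scnn1g and Scnn1b (-1.32, SE 0.25). Fatty acid and phospholipid synthesis had 7 of 18 lower and 2 higher, and 8 lower and 3 higher adjusted over the list alone (adjusted p = 0.0479, adjusted p = 0.501 with an estimated correlation), with Scd1, Lpin1 at -1.19 (SE 0.28), Gpam at -0.64 (SE 0.19) and Elovl1 at -0.58 (SE 0.11). The epithelial lineage list was not called, with 4 of 18 higher and 2 lower. The distal tip factor Sox9 (1.30, SE 0.24) and Epcam (0.85, SE 0.16) rose and the keratins Krt19 (-1.19, SE 0.17) and Krt8 (-0.48, SE 0.13) fell. Ciliated cell genes had 0 of 7 called, and of 5 neuroendocrine genes Nnat (0.68, SE 0.13) and Meis2 (0.39, SE 0.10) rose.

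In the mesenchyme and its matrix, genes moved both ways at E18.5. Lipofibroblast genes had 8 of 15 lower and 1 higher, and 9 lower and 1 higher adjusted over the list alone (median -0.68, adjusted p = 0.000764, adjusted p = 0.193 with an estimated correlation). In it Inmt, Zbtb16, Dgat2 (-1.91, SE 0.21) and the leptin receptor Lepr (-1.59, SE 0.12) fell. Fibrillar collagen and interstitial matrix genes had 10 of 29 lower and 4 higher, and 11 lower and 4 higher adjusted over the list alone (adjusted p = 0.0296, adjusted p = 0.501 with an estimated correlation), with Spon1 and Timp3 (-1.29, SE 0.22) lower and Vcan and Fmod (1.67, SE 0.25) higher. Basement membrane genes had 7 of 22 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.0449, adjusted p = 0.589 with an estimated correlation). In it Col4a3 (-2.91, SE 0.43), Col4a4 (-1.21, SE 0.25) and Nid2 (-0.82, SE 0.14) fell and Col18a1 rose (1.28, SE 0.28). Among elastic fibre genes, a list not called, Eln fell (-1.33, SE 0.13), as did Lox (-0.87, SE 0.11), and Fbn2 (1.64, SE 0.24) and Fbln1 (1.02, SE 0.24) rose. The lung mesenchyme list was not called, with 6 of 22 higher and 5 lower. Prrx2 (1.38, SE 0.27), the hedgehog effector Gli1 (1.26, SE 0.30) and Prrx1 (1.23, SE 0.13) rose and the mesenchymal factor Tcf21 (-0.75, SE 0.09) fell. Without E18.5 control replicate 3 the fibrillar collagen call was lost (adjusted p = 0.188), and the fibrillar call was also lost without mutant replicate 3 (0.0774). The basement membrane call was lost without control replicates 1, 2, 3 or 5 or mutant replicates 3 or 4 (0.0514 to 0.0846).

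Endothelial markers were lower in the mutants at E18.5, with 13 of 23 lower and 1 higher, and 16 lower and 1 higher adjusted over the list alone (median -0.40, adjusted p = 2.02e-06, adjusted p = 0.239 with an estimated correlation). Besides Car4, Robo4 (-0.75, SE 0.14), Emcn (-0.74, SE 0.10) and Icam2 (-0.73, SE 0.10) fell. Lymphatic endothelium had 4 of 5 lower, also adjusted over the list alone (adjusted p = 0.00259, adjusted p = 0.239 with an estimated correlation), namely Lyve1 (-1.12, SE 0.14), Pdpn (-0.72, SE 0.10), Nrp2 (-0.53, SE 0.19) and Flt4 (-0.53, SE 0.13). Mesothelial genes had 6 of 9 lower and 1 higher, and 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.0107, adjusted p = 0.239 with an estimated correlation), such as Msln (-1.70, SE 0.63), Gpm6a (-0.93, SE 0.16) and Rspo1 (-0.85, SE 0.18), but this call was lost without E18.5 control replicate 3 (adjusted p = 0.0578). The fatty acid call was lost without any one of the E18.5 controls but replicate 3, or without mutant replicates 1, 2 or 4 (0.0505 to 0.0964). Lists without a call included smooth muscle (3 of 19 higher, 2 lower), pericytes (2 of 12 higher, 4 lower, and 3 and 4 adjusted over the list alone) and macrophages (1 of 19 higher, 1 lower), the last of which passed without mutant replicate 3 (0.0406). In smooth muscle, Myocd (0.87, SE 0.23), Mustn1 (0.78, SE 0.17) and Pdlim3 (0.60, SE 0.20) rose and Aspn (-0.88, SE 0.18) fell. Among pericyte genes Abcc9 (0.83, SE 0.29) and Rgs5 (0.76, SE 0.19) rose and Trpc6 (-1.20, SE 0.27) and Cspg4 (-0.76, SE 0.28) fell. Of the macrophage genes Aif1 (0.70, SE 0.21) rose and Pf4 (-0.43, SE 0.12) fell. Of 7 erythroid genes 2 were lower, Hbb-y (-2.06, SE 0.66, but -1.31 without E18.5 control replicate 3) and Alas2 (-0.78, SE 0.19), and 1 higher, Car2 (0.28, SE 0.07), with 4 lower and 1 higher adjusted over the list alone. Of 15 cardiac muscle genes 3 were higher, Myl3 (1.78, SE 0.42), Smpx (1.58, SE 0.12) and Myl2 (1.46, SE 0.31), and 1 lower, Ryr2 (-1.32, SE 0.30).

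Signalling lists at E18.5 were not called by camera, although single members changed. The exact permutation test of list means passed 4 of them: Wnt (0.30, adjusted p = 0.0357) and hedgehog signalling (0.28, 0.0357) were higher, and FGF signalling (-0.17, 0.0357) and the IGF system (-0.19, 0.0429) were lower, each with 4 of 5 mutants beyond the controls. In Wnt signalling 6 of 18 were higher and 2 lower (7 and 3 adjusted over the list alone), with Wif1 (1.02, SE 0.19) and Wnt11 (0.94, SE 0.16) up and Nkd1 (-1.03, SE 0.21) down. Hedgehog signalling had 3 of 9 higher, Gli1, Smo (0.63, SE 0.10) and Gli2 (0.52, SE 0.13). Among FGF genes, 2 of 15 were higher and 6 lower, including Fgfr4 (-0.93, SE 0.18), Fgfbp1 (-0.81, SE 0.18), Fgf7 (-0.66, SE 0.17) and Etv5 (0.59, SE 0.14). The TGF-beta list had 6 of 18 higher and 3 lower (6 and 4 adjusted over the list alone), with Tgfb2 (0.93, SE 0.15), Tgfb3 (0.90, SE 0.15) and Bmp5 (0.69, SE 0.11) up and Bmp2 (-0.99, SE 0.33) down. In the IGF system 3 of 12 were higher and 4 lower, with Igfbp3 (-1.97, SE 0.27), Igfbp6 (-1.92, SE 0.33) and Igfbp7 (-0.74, SE 0.15) down and Igfbp2 up. Its median was 0.11 and its mean -0.19. Retinoid signalling had 1 of 10 higher and 3 lower (1 and 4 adjusted over the list alone), with a median of 0.07 and a mean of -0.09, with Dhrs3 (-0.64, SE 0.22), Aldh1a1 (-0.60, SE 0.14) and Rarg (-0.24, SE 0.09) down and Rdh10 (0.21, SE 0.08) up. Hypoxia and glycolysis had 3 of 16 higher and 5 lower, with Adm (-2.43, SE 0.20), Ndrg1 (-1.30, SE 0.34), Vegfa (-0.98, SE 0.20) and Hk2 (-0.78, SE 0.17) down, and passed without mutant replicates 1 or 2 (adjusted p = 0.0467 and 0.0401). Inflammation and interferon had 2 of 9 higher and 3 lower (2 and 5 adjusted over the list alone), with Saa3 (-1.84, SE 0.18) and Icam1 (-0.43, SE 0.16) down and Ccl2 (0.96, SE 0.31) and Vcam1 (0.51, SE 0.10) up. Sterol synthesis had 1 of 13 higher.

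Of the 139 genes named for E18.5, 17 lost their call without some array. Leaving out any one of E18.5 controls 1, 2, 4 and 5 and E18.5 mutants 1, 2 and 4 ended the calls of Hc (-1.40 to -1.08), Chad (-1.12 to -0.85), Dhrs3 (-0.65 to -0.54) and Cyp2f2 (-0.72 to -0.58, also without E16.5 control 4 or E16.5 mutant 3). Msln lost its call without the same arrays (-1.70 to -1.58) and also without E16.5 controls 2 or 4 or E16.5 mutant 3. Without E18.5 controls 1, 2 or 5 or E18.5 mutants 1, 2 or 4 the same held for Scd1 (-1.23 to -0.97), Bmp2 (-0.91 to -0.85), Icam1 (-0.44 to -0.32) and Nrp2 (-0.56 to -0.41, also without E18.5 mutant 5). The same 3 controls ended the calls of Ccl2 (0.91 to 0.92), Pdlim3 (0.47 to 0.56, also without E18.5 mutants 1 or 2), Abcc9 (0.60 to 0.82, also without mutants 1, 4 or 5) and Cspg4 (-0.72 to -0.67, also without mutants 1, 2 or 3). Rarg lost its call without E18.5 controls 1, 2 or 3 or E18.5 mutants 2 or 3 (-0.25 to -0.18). Aif1 lost it without E18.5 control 2 (0.60) and Hbb-y without E18.5 mutant 3 (-1.69). Rdh10 lost it without any one of 14 arrays (0.16 to 0.22), namely E16.5 controls 1 and 4, E18.5 controls 1, 3, 4 and 5, and mutants 2 to 5 of either stage.

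With stage position as a covariate, chosen after the values were seen, camera at the preset correlation called 8 lists at E18.5, 3 higher and 5 lower. In all, without that covariate, camera called 16 of 36 lists at E18.5, 2 higher and 14 lower, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. The exact permutation test of list means called 20 of 36, including 13 of those 16, the exceptions being type II cells (adjusted p = 0.0769), fibrillar collagen (0.0649) and fatty acid synthesis (0.0649). Of the 13, 7 had the list means of 5 of 5 mutants beyond all controls, 3 had 4 of 5 (club cells, lymphatic endothelium and DNA replication) and 3 had 3 of 5 (basement membrane, mitosis and ion transport). The 7 that passed only the permutation test were the growth arrest, Wnt, hedgehog, FGF and IGF lists, erythroid genes (-0.65, adjusted p = 0.0357) and hypoxia genes (-0.36, adjusted p = 0.0318). In the erythroid list, which holds the embryonic globins Hbb-y and Hba-x, E18.5 control replicate 3 had a mean of 9.11, against 7.79 to 8.34 in the other E18.5 controls. Median and mean differed in sign in the lists of lung mesenchyme, retinoid signalling and the IGF system. Lists too small to test had few measurable members: granulocytes 3, skeletal muscle 2, liver 2, brown fat 1, oesophagus 1, neurons and Schwann cells 3, and thymus 0. Of these 12 genes, 4 were called at E18.5, all lower: 1 of skeletal muscle, 1 of oesophagus and 2 of neurons and Schwann cells.

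**Figure D2:**
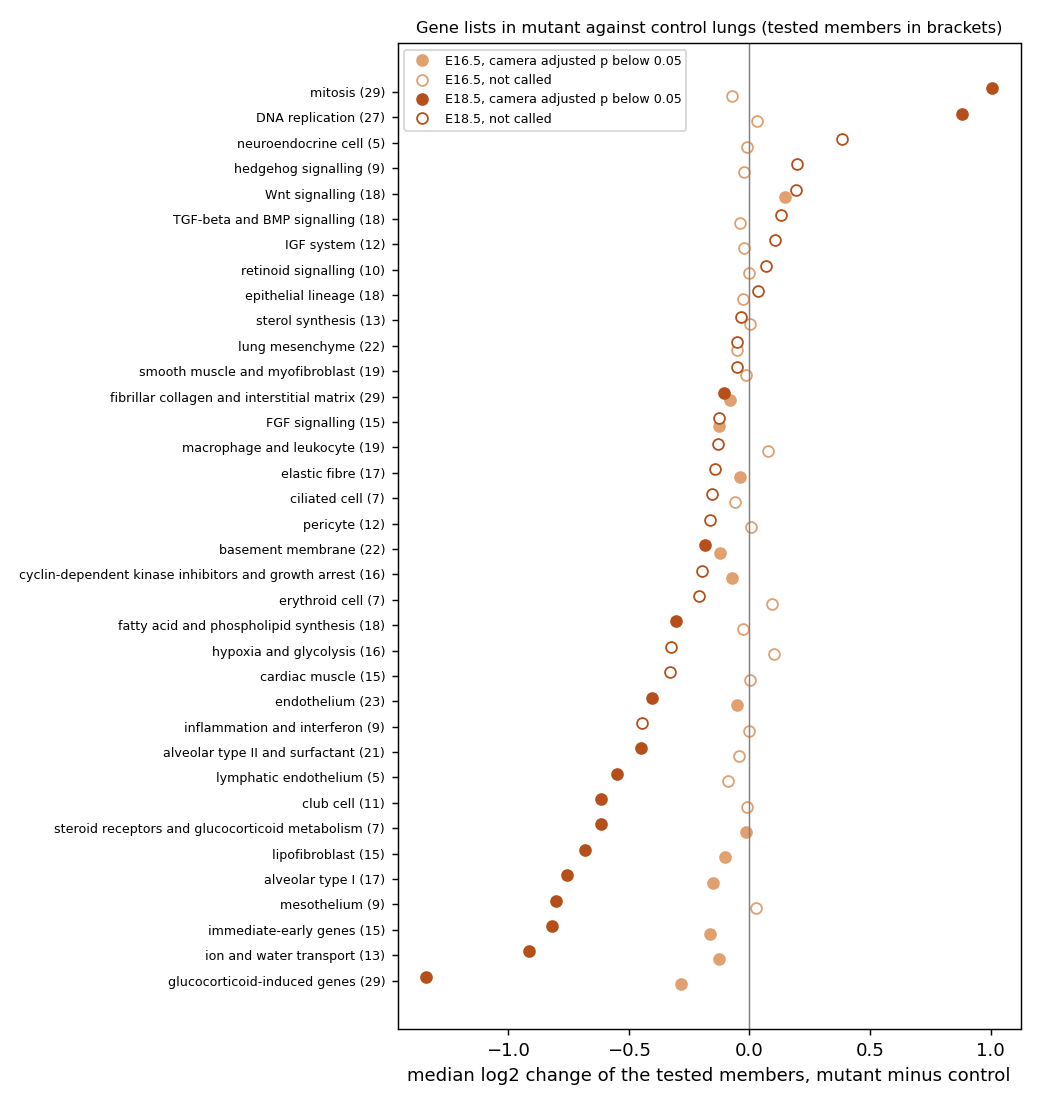
Median log2 change, mutant minus control (x axis), of the tested members of each of 36 gene lists (y axis, members in brackets), at E16.5 (light) and E18.5 (dark); filled points passed camera at the preset correlation. At E18.5 the lists ranged from -1.34 for glucocorticoid-induced genes to 1.01 for mitosis.

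The mutant effects at both stages were compared to ask whether the same genes respond. Called at both were 18 genes in the same direction: Rspo2, Prrx1, Nr1d2 and Nr2f1 higher, and Nr3c1, Hsd11b1, Cldn1, G0s2, Per1, Hif3a, Dgat2, Lpar1, Ppp1r14a, Lox, Ogn, Mgp, Acaa2 and Gstm2 lower. The last 3, Mgp (-0.47), Acaa2 (-0.35) and Gstm2 (-0.26 at E16.5), were named after their values were seen, to complete the list. Chance would give 0.745 shared rises against 4 found (one-sided Fisher exact p = 0.00120) and 2.54 shared falls against 14 found (p = 5.38e-10), and 0 genes were called in opposite directions. With no filter on dim genes 2 of 7 rises (one-sided Fisher exact p = 0.187) and 13 of 16 falls (exact p = 7.96e-11) were shared, so the overlap of rises depended on the filter. At an unadjusted p under 0.01, 21 of 48 rises and 52 of 68 falls were shared and 2 genes went in opposite directions. Across all 8068 genes, which are not independent replicates, the effects correlated with Pearson r = 0.274 and Spearman rho = 0.347.

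The change from E16.5 to E18.5 in controls sets the background of normal maturation. The chitinase-like gene Chil1 rose by 9.22 (SE 0.65, adjusted p = 1.08e-09), from 2.64 ± 0.20 to 11.86 ± 0.87 (SD, n = 5). The surfactant protein Sftpd (8.26, SE 0.48), complement Hc (7.94, SE 0.50), the calcium-binding S100g (7.32, SE 0.73), the club cell secretoglobin Scgb1a1 (6.92, SE 0.45), the desaturase Scd1 (6.91, SE 0.42), Dpep1 (6.78, SE 0.44), Aqp5 (6.72, SE 0.33), Pon1 (6.71, SE 0.92) and Msln (6.34, SE 0.63) rose most after it. The E16.5 means of Chil1, Hc, S100g, Dpep1, Aqp5 and Pon1 were dim, so the sizes of their rises, and their order, are limited by the floor of the values. The deepest falls were Cldn6 (-5.00, SE 0.50), Col9a3 (-4.29, SE 0.49), Lrr1 (-4.06, SE 0.27), Col9a1 (-4.04, SE 0.50), Cfi (-3.96, SE 0.27), Eme1 (-3.88, SE 0.38), Exo1 (-3.81, SE 0.36), Mcm10 (-3.75, SE 0.31), Psrc1 (-3.72, SE 0.41) and Cdc45 (-3.64, SE 0.35), several of them genes of DNA replication and repair. The E18.5 means of Col9a3, Eme1, Exo1 and Cdc45 were dim, which limits their falls in the same way. In each of these 20 genes all 5 E18.5 controls lay beyond all E16.5 controls (0.00794 by chance for an unselected gene, which these are not). Of 8068 genes 5718 passed, 2851 higher and 2867 lower at E18.5. In mutants 4538 passed, 2313 higher and 2225 lower. With blood as a covariate 4766 passed in controls and 1342 in mutants. The blood value is the mean of the erythroid list, which holds embryonic globins that fall over development. In mutants it was 5.26 to 5.59 at E16.5 and 4.66 to 4.88 at E18.5, so that fit cannot separate blood from stage in mutants.

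Lists that rose over development in controls included type II cells (20 of 21 members, median 3.56, adjusted p = 1.25e-08, adjusted p = 0.285 with an estimated correlation), type I cells (16 of 17, with 1 lower, adjusted p = 4.27e-07, adjusted p = 0.285 with an estimated correlation), club cells (11 of 11, median 4.16) and ciliated cells (7 of 7), with Cbr2 at 5.21 (SE 0.37) and Tppp3 at 2.57 (SE 0.17). Club cells had an adjusted p = 4.37e-06, adjusted p = 0.285 with an estimated correlation, and ciliated cells adjusted p = 0.00888, adjusted p = 0.383 with an estimated correlation. Glucocorticoid-induced genes rose in 23 of 29, with 2 lower, and in 24 with 2 lower adjusted over the list alone (median 1.64, adjusted p = 3.09e-06, adjusted p = 0.285 with an estimated correlation), with Klf9 at 2.99 (SE 0.18). Macrophage genes rose in 18 of 19 (adjusted p = 1.12e-05, adjusted p = 0.285 with an estimated correlation), with Ptprc at 2.48 (SE 0.29), and endothelial genes in 21 of 23 with 1 lower (adjusted p = 6.82e-06, adjusted p = 0.285 with an estimated correlation). Mitosis and DNA replication fell in 29 of 29 and 27 of 27 members (adjusted p = 3.10e-10 and 3.78e-13, adjusted p = 0.345 and 0.285 with an estimated correlation), with the checkpoint kinase Ttk at -3.01 (SE 0.35) and Ccne1 at -3.51 (SE 0.22). In these lists but the glucocorticoid one, the counts were the same adjusted over the list alone. The embryonic globins Hbb-y (-3.45, SE 0.66) and Hba-x (-3.48, SE 0.71) fell.

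Camera called 19 of 36 lists in controls (17 up, 2 down) and 20 in mutants (17 up, 3 down), with 0 in either at an estimated correlation (3 and 6 at an unadjusted p under 0.05), and all 19 of the controls passed the exact permutation test. The elastic fibre call in controls (adjusted p = 0.0447, adjusted p = 0.345 with an estimated correlation) was lost without E16.5 control replicate 2 (0.0592) or E18.5 control replicate 3 (0.0789). The call of cardiac muscle (adjusted p = 0.0316, adjusted p = 0.507 with an estimated correlation) was lost without E16.5 control replicate 5 (0.0562). The sterol synthesis call in mutants (adjusted p = 0.0410, adjusted p = 0.444 with an estimated correlation) was lost without E16.5 mutant replicates 1 or 2 or E18.5 mutant replicates 4 or 5 (0.0556 to 0.0926). TGF-beta signalling passed in mutants only without E16.5 mutant replicate 4 (0.0464) or E18.5 mutant replicate 3 (0.0477).

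The interaction tested which mutant effects differ between the stages. The effect on Slc10a6 was lower at E18.5 than at E16.5 by a log2 difference of -5.40 (SE 0.24, adjusted p = 4.56e-11), on Lims2 by -3.74 (SE 0.28) and on Slc7a10 by -3.69 (SE 0.38). It was also lower on the folate enzyme Aldh1l1 by -2.52 (SE 0.26), on the growth factor Bmp6 by -2.43 (SE 0.21), on Sult5a1 by -2.23 (SE 0.24), on the natriuretic peptide receptor Npr3 by -2.0 (SE 0.21), on the prostacyclin synthase Ptgis by -1.90 (SE 0.19) and on the proton pump Atp12a by -1.40 (SE 0.14). For Cntn1 the effect was higher at E18.5, by 2.56 (SE 0.27). Of these 10 genes, 7 were dim in both groups at E16.5 (all but Ptgis, Npr3 and Sult5a1). For the 6 of them with a lower effect, a fall at E16.5 had no room to show, and the difference restates the E18.5 fall. In all, 678 of 8068 genes passed, 292 with a higher and 386 with a lower effect at E18.5, of which 3 and 79 were dim in both E16.5 groups. The number was 1445 without E18.5 control replicate 3, and 420 without E16.5 control replicate 3, 411, 424 and 393 without E18.5 control replicates 1, 2 and 5, 450 and 439 without E16.5 mutant replicates 4 and 5, and 412 and 408 without E18.5 mutant replicates 2 and 4; the 10 named genes passed in each of these fits.

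Camera called 12 of 36 lists for the interaction, 2 higher and 10 lower at E18.5, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. Mitosis (10 of 29 members higher, 28 adjusted over the list alone) and DNA replication (18 of 27, 25 adjusted over the list alone) had the calls with the smallest p (adjusted p = 4.48e-13 and 9.54e-15, adjusted p = 0.321 with an estimated correlation in both). Glucocorticoid-induced genes had 12 of 29 lower and 1 higher, and 15 lower and 1 higher adjusted over the list alone (adjusted p = 2.98e-09, adjusted p = 0.321 with an estimated correlation). Of the 12, 3 were dim in both E16.5 groups. Type I cells had 6 of 17 lower and 1 higher, and 8 lower and 1 higher adjusted over the list alone (adjusted p = 7.99e-05, adjusted p = 0.321 with an estimated correlation). Mesothelium (adjusted p = 0.00782, adjusted p = 0.321 with an estimated correlation) lost its call without E18.5 control replicate 3 (0.0706), and fatty acid synthesis (adjusted p = 0.0466, adjusted p = 0.563 with an estimated correlation) without any one of 12 arrays (0.0527 to 0.106), namely E16.5 controls 1, 2 and 3, E18.5 controls 1, 4 and 5, E16.5 mutants 3, 4 and 5 and E18.5 mutants 1, 2 and 4. Type II genes, not called (adjusted p = 0.0933), passed without E16.5 control 5, E16.5 mutants 1 or 2 or E18.5 mutants 3 or 5 (0.00456 to 0.0431). Hypoxia genes passed without E18.5 control 5, E16.5 mutant 1 or E18.5 mutants 1 or 2 (0.0307 to 0.0375), macrophage genes without E18.5 mutants 3 or 5 (0.0132 and 0.0495), and hedgehog genes without E16.5 control 2 (0.0499).

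Genes that change over development were compared with the genes that differ in E18.5 mutants. The slope of the mutant effect on the developmental change was -0.382 (jackknife SE 0.0853, two-sided permutation p = 0.0200 over 100 regroupings, of which 1 other had a larger slope, 0.428 in size), with a correlation of -0.768 across genes: genes that rise in control lungs tended to be lower in mutants, and genes that fall tended to be higher. On the developmental axis of the controls, where 0 is the E16.5 and 1 the E18.5 control mean, E18.5 mutants had a mean position of 0.606 ± 0.150 (SD, n = 5) and E18.5 controls 0.990 ± 0.163. The difference was -0.385 (two-sided exact permutation p = 0.0238). One control, replicate 3, lay at 0.704, among the mutants, and without it the difference was -0.425 and the slope -0.427, values with no test, since that array was set aside for its position. At E16.5 the mutants differed from the controls by -0.0352 (exact permutation p = 0.643).

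**Figure D3:**
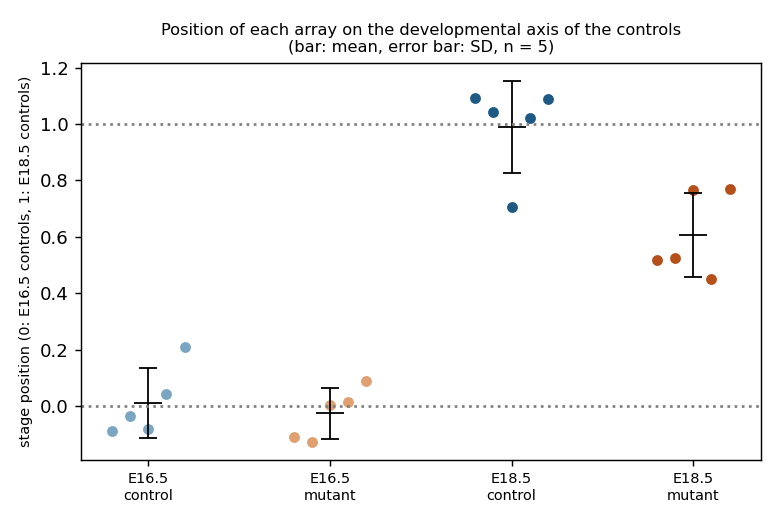
Position of each array on the developmental axis of the controls (y axis, 0 for the E16.5 and 1 for the E18.5 control mean) by group (x axis); bars are means and error bars SD over 5 animals. E18.5 mutants lay at 0.452 to 0.769, and E18.5 control replicate 3 lay at 0.704.

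**Figure D4:**
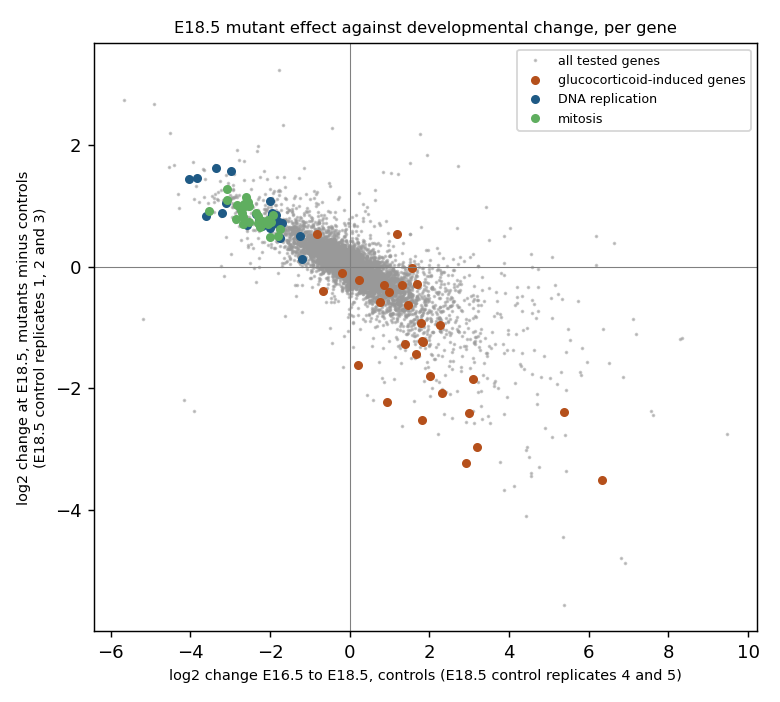
Log2 effect of the mutation at E18.5, from control replicates 1 to 3 (y axis), against the log2 change from E16.5 to E18.5 in controls, from E18.5 control replicates 4 and 5 (x axis), for 8068 genes. DNA replication (blue) and mitosis genes (green) fell over development and were higher in mutants, and many glucocorticoid-induced genes (red) lay below the trend of the other genes.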

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

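The tests of the origin of E18.5 control replicate 3 and of the position of the E18.5 mutants were chosen after the results were seen, and the tests of sex and of other splits of the arrays before.

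One control animal stood out in this study. E18.5 control replicate 3 lay at a stage position of 0.704, apart from the other 4 E18.5 controls, and its Nr3c1 value of 9.02 was apart from the 9.47 to 9.57 of the others. It stood apart from its group in 80 named genes and in 7 gene list means. Chance marks about 1 in 20 groups in this way. Of 936 groups of named gene values 136 held such an array (46.8 by chance), and of 144 groups of list means 14 did (7.20 by chance). E16.5 control replicate 5, the only female of its group and the array with its highest stage position (0.21), stood apart in 16 named genes and 4 list means. Other counts of named genes were 3, 3 and 2 for E16.5 control replicates 1, 3 and 4; 3, 3, 1, 4 and 2 for E16.5 mutant replicates 1 to 5; 3, 2 and 1 for E18.5 control replicates 1, 2 and 4; and 1, 2, 3, 6 and 1 for E18.5 mutant replicates 1 to 5. E16.5 control replicates 2 and 4 and E18.5 control replicate 4 stood apart in 1 list mean each. In E16.5 control replicate 2 the mean of the poly-A spike-in controls was 7.11, apart from its group.

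Of the explanations for E18.5 control replicate 3, a mixture of E16.5 and E18.5 control RNA was set against the shares of E16.5 RNA that 195 falling and 401 rising genes would need. These were 0.207 and 0.465 on the linear scale, a difference of -0.258 (95% bootstrap interval over the genes of this 1 array, -0.307 to -0.204), but 0.398 and 0.237 on the log2 scale, and as the values were not shown to be linear in RNA, a mixture and a younger embryo cannot be told apart. A mutant lung under a control name is argued against by Nr3c1, which lay 0.97 above the highest E18.5 mutant. A younger embryo may explain the array: its embryonic globin Hbb-y read 12.3, within the 11.7 to 13.5 of all E16.5 embryos and above the 7.95 to 8.95 of the other E18.5 controls. A biological difference in pace of development between embryos of one age was not tested and stays open.

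The position of the E18.5 mutants between the control stages was weighed next. Embryos collected younger should hold more embryonic globin, at a log2 difference of 1.82 in Hbb-y for their stage position, and of 1.90 in Hba-x, but against the 4 controls without replicate 3 they were at -1.31 (SE 0.48, adjusted p = 0.0366) and -0.84 (SE 0.44, adjusted p = 0.136). Erythroid genes as a list were lower too (-0.65, with all controls), but that list holds these 2 globins. The mean of its 5 other genes was at -0.18 (SE 0.11) against the controls without replicate 3. Less blood does not account for the shortfall, since relative to that mean the 2 globins were at -1.13 (SE 0.55) and -0.66 (SE 0.35). A delay that holds back every gene by the same share is argued against by the 20 rising genes of the glucocorticoid list. They reached a median share of 0.195 of their developmental rise in mutants, while all 1015 rising genes reached 0.638. The 2.5th percentile of 10000 random lists of the same size was 0.506. A uniform delay in time is not decided by these shares. With 2 stages the time course of each rise is not known, and genes that rise late would reach a smaller share. A biological effect of the mutation on lung maturation stays open and was not tested beyond these values.

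At E16.5 the mutants were 5 females and the controls 1 female and 4 males, so sex was tested as the source of the 20 calls. Among E18.5 animals, the median female minus male difference in these genes, taken along the E16.5 direction, was a share of 0.112 of the median E16.5 effect. Its 95% interval of 0.0087 to 0.175 came from resampling the genes, so it leaves out the spread between animals. In the limma sex test there 0 of 20 passed, but only 4 of all genes tested did, so this test could detect little and decides nothing here. Over all 20 genes the median size of the change was 0.672 without and 0.712 with sex as a covariate, and the median SE 0.112 and 0.131. The covariate ended 12 calls, of which 5 had a smaller change (Dgat2 went from -1.34 to -0.96) and 7 a larger one, with a median size of 0.588 before and 0.613 after and a median SE of 0.105 before and 0.127 after, so the wider error ended calls in genes whose change did not shrink and a smaller change had a part in others. The covariate is estimated within groups that hold both sexes, mostly from E18.5 arrays, so it and the E18.5 difference are largely the same evidence. By the sizes of these medians, without a test over animals, a sex effect shared with E18.5 is argued against as the main source. This holds for most of the change in these genes as a set, but not for each gene. A sex effect present only at E16.5 stays open.

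Chance was tested by other splits of the same arrays. At E16.5, 2 of 100 splits, the real one included, had as many calls as the real 20, which makes chance less likely but does not exclude it. The highest other split had 117, which points to a structure of the samples: it joined control replicates 4 and 5 with mutant replicates 3, 4 and 5 against the other 5 arrays. The joined arrays had stage positions of 0.0048 to 0.21 and the other 5 of -0.13 to -0.034. That split thus followed stage position within E16.5, and it gave more calls than genotype did. At E18.5 only the real split had as many calls (1 of 100, real 2784, highest other 2680, with control replicate 3 and mutant replicate 5 exchanged). The same held for development in controls (1 of 100, 5718 against 4685, with E16.5 control replicate 5 and E18.5 control replicate 3 exchanged) and in mutants (1 of 100, 4538 against 2360). Chance is thus argued against for each of them. For the interaction 4 of 100 splits, the real one included, had as many as the real 678, which makes chance less likely but does not exclude it. The highest other had 1415, but it exchanges the genotype of all 10 E18.5 arrays (and of E16.5 control replicate 3 and mutant replicate 2), so it carries the E18.5 genotype effect with its sign turned.

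Mutant effects that differed between the stages by the interaction test covered 678 genes. The 10 with the smallest p were Slc10a6 (-5.40), Lims2 (-3.74), Bmp6 (-2.43), Atp12a (-1.40), Ptgis (-1.90), Aldh1l1 (-2.52), Slc7a10 (-3.69), Npr3 (-2.0), Sult5a1 (-2.23) and Cntn1 (2.56), as E18.5 effect minus E16.5 effect. All but Ptgis, Npr3 and Sult5a1 were dim in both E16.5 groups, so that for Slc10a6, Lims2, Bmp6, Atp12a, Aldh1l1 and Slc7a10 a fall at E16.5 had no room to show and the value restates the E18.5 fall. Of the 678 genes, 82 were dim in both E16.5 groups. Camera called 12 lists at the preset correlation and 0 with an estimated one. In these 12 lists, the median difference was -0.70 for glucocorticoid-induced genes, -0.56 for type I cells, -0.59 for club cells, -0.30 for lipofibroblasts, -0.83 for mesothelium, -0.36 for endothelium, -0.52 for lymphatic endothelium, 1.09 for mitosis, 0.86 for DNA replication, -0.37 for ion transport, -0.23 for fatty acid synthesis and -0.52 for immediate-early genes. Of the 139 genes named for E18.5, 68 passed this test. Among 993 tested probe sets that do not name a single gene, and so entered no comparison, 294 were called at E18.5, 196 higher and 98 lower.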

How the results depend on the processing

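The covariates for stage position and poly-A controls, the sex covariate without genes on X and Y or for the E16.5 lists, and the permutation of list means were chosen after the data were seen; the other alternatives were planned. The 20 calls at E16.5 became 9 with only the arrays compared (fewer degrees of freedom), 43 with array weights, 8 with a sex covariate (8 without genes on X and Y) and 11 at an adjusted p under 0.01. The 2784 at E18.5 became 584 with a stage position covariate (which nearly coincides with genotype there), 1645 at an adjusted p under 0.01 and 1060 at 1.5-fold or more. The 5718 over development in controls became 8586 with all probe sets (more features tested) and 3171 at 1.5-fold. The 4538 in mutants became 1342 with a blood covariate (which separates the stages fully in mutants) and 2057 at 1.5-fold. The 678 of the interaction became 2244 with array weights, 439 with sex, 1830 with blood and 166 at an adjusted p under 0.01. Genes called at both stages numbered 73 instead of 18 at an unadjusted p under 0.01 (more genes). Camera list calls became 0 at E16.5, 0 at E18.5 and 0 over development in controls with an estimated correlation, and the 16 at E18.5 became 8 with stage position. The permutation of list means called 0 lists at E16.5 instead of 13 and 31 over development in controls instead of 19. Beyond the reasons in brackets and the stricter thresholds, the cause was not tested.

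Leaving out each array in turn gave 13 (mutant replicates 4 and 5) to 22 calls at E16.5, 2197 to 3355 at E18.5, 5466 to 5809 and 4108 to 4753 over development in controls and mutants, and 393 (E18.5 control replicate 5) to 1445 (E18.5 control replicate 3) for the interaction. List calls were 4 (without E16.5 control replicate 5) to 15 at E16.5, 13 to 16 at E18.5 and 18 to 19 over development, and the slope -0.427 to -0.344. A named gene lost its call without some array in 6 cases at E16.5, 17 at E18.5, 2 over development (Actc1, 0.45 to 0.58, and Slc4a1, 0.66 to 0.79) and 0 for the interaction. Replicate numbers were checked for pairing: correlations of arrays with the same number were -0.0634 to 0.580 at E16.5 and -0.437 to 0.176 at E18.5, with 4 of 5 and 1 of 5 controls closest to the mutant of their own number. As 1 pair at E16.5 was below 0 and the sources used here give the numbers no meaning, they were not taken as pairs, although the E16.5 values leave a shared factor open. With the replicate block, 12 genes passed at E16.5 (0 higher, 12 lower) and of the named genes Rspo2, Prrx1, Nr1d2, Nr2f1, Igsf5, Lox and Ogn lost their calls. In that fit 2751 passed at E18.5 and 443 for the interaction, and 12 lists at E16.5 (0 higher, 12 lower).

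Over all alternatives, named genes kept direction and side of the threshold in 632 cases at E16.5, 3071 at E18.5, 3404 over development and 312 for the interaction. They lost the call in 83, 221, 23 and 0 cases, gained it in 1 (Fgfr4 at E16.5 with array weights) and reversed in 15. All reversals were at E18.5 with the stage position covariate: Scara3 (-0.25), Akr1c14 (0.21), Hc (0.83), Scd1 (0.53), Lyz2 (0.17), Chad (0.38), Cyp2f2 (0.077), Pdlim3 (-0.0095), Msln (0.58), Hmmr (-0.11), Kif20a (-0.037), Dhrs3 (0.21), Bmp2 (0.41), Gpam (0.23) and Icam1 (0.16). That covariate is computed from the same values and nearly coincides with genotype at E18.5, so this fit cannot separate the mutant effect from stage position. The cause of the reversals was not tested. Signal over background limits changes into or out of dim values, as in Slc10a6, Inmt, Lims2, Slc7a10 and Chil1, whose size depends on the floor of the values.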

Other observations

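Genes of the circadian clock, histocompatibility genes and cartilage genes were looked at after their values were seen.

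Of 13 circadian clock genes, 9 were called in E18.5 mutants and 2 at E16.5. Per1 fell by 2.5 (SE 0.27) and Per2 fell by 1.40 (SE 0.27) at E18.5, and Npas2 (-0.84), Nfil3 (-0.42), Cry2 (-0.38), Tef (-0.37) and Arntl (-0.29) were lower, while Nr1d2 (0.69) and Dbp (0.58) were higher. Per3 (-0.20), Cry1 (-0.28), Clock (-0.37) and Bhlhe40 (-0.54) did not pass. Leaving out single E18.5 arrays ended the calls of Cry2 (without control replicates 1 or 2, -0.33 and -0.34), Tef (controls 1, 2, 4 or 5 or mutants 2 or 4, -0.36 to -0.32) and Arntl (controls 1, 4 or 5 or mutants 1 to 4, -0.29 to -0.24). At E16.5 Per1 (-1.53) and Nr1d2 (0.63) passed, Per1 not without mutant replicate 4 (-1.38). The hour of collection is not in the sources used here.

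Class II histocompatibility genes were higher in E18.5 mutants: H2-Eb1 (2.14, SE 0.28), H2-Aa (1.64, SE 0.25) and H2-Ab1 (1.60, SE 0.27), while Cd74 (1.06, SE 0.49, adjusted p = 0.101) and the class I genes H2-K1 (-0.33) and H2-D1 (-0.32) did not pass. All of these genes rose over development in controls, by 3.56 for Cd74, 2.72 for H2-Aa, 1.70 for H2-Eb1, 0.89 for H2-Ab1, 1.90 for H2-D1 and 1.80 for H2-K1. The class II rise in mutants thus ran with development and not against it.

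Genes chosen as cartilage genes did not move together in E18.5 mutants. Chad is also in the club cell list and Sox9 in the epithelial lineage list, so their values in the whole lobe need not come from cartilage. Col9a1 (3.26), Col9a3 (2.34) and Sox9 (1.30) were higher, Hapln1 (-0.81) and Chad (-1.07) were lower, and Col2a1 (0.45), Col11a1 (0.39), Matn4 (0.53), Sox5 (-0.24), Sox6 (0.33), Fgfr3 (-0.29) and Cnmd (-0.00) did not pass. The Chad call was lost without any of E18.5 controls 1, 2, 4 and 5 and mutants 1, 2 and 4 (-1.12 to -0.85), and Chad changed sign with stage position as a covariate (0.38). With that covariate Col9a1 (1.49, adjusted p = 0.0957), Col9a3 (0.48, 0.570), Sox9 (0.49, 0.245) and Hapln1 (-0.48, 0.262) did not pass either, while Col11a1 (-1.26, adjusted p = 0.0320) and Matn4 (1.07, 0.0364) did. Over development in controls Col9a3 (-4.29), Col9a1 (-4.04), Col11a1 (-2.72), Cnmd (-2.29), Sox9 (-1.98), Col2a1 (-1.92) and Sox6 (-0.65) fell, Chad (4.33), Matn4 (1.59) and Fgfr3 (0.78) rose, and Sox5 (-0.14) and Hapln1 (-0.05) did not pass.

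The median share of the developmental rise that rising genes reached in E18.5 mutants was computed for each list with 5 or more such genes, and differences between lists were not tested, apart from the glucocorticoid list against random lists. The values were 0.925 for ciliated cells (5 genes), 0.874 for macrophages (12), 0.856 for type II cells (19), 0.799 for inflammation (7), 0.769 for fatty acid synthesis (9), 0.753 for club cells (11), 0.727 for cardiac muscle (12), 0.705 for elastic fibre (8) and 0.672 for basement membrane (9). They were 0.617 for type I cells (14), 0.614 for ion transport (11), 0.597 for growth arrest (5), 0.586 for endothelium (11), 0.476 for lipofibroblasts (8), 0.470 for immediate-early genes (10), 0.412 for fibrillar collagen (7) and 0.195 for glucocorticoid-induced genes (20).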
